A study of Mus musculus with 9 samples.

How the data were processed

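The series holds 9 RNA-seq libraries of mouse pancreatic ductal cells, 3 for each of 3 genotypes: WT (no floxed Ctnnd1 allele), HET (1 floxed allele) and NULL (2 floxed alleles), all with a Cre-activated Kras G12D allele. Per the labels' protocols, the cells were grown on plastic in medium for ductal cells, transduced with a lentivirus carrying Cre recombinase, and total RNA was extracted with a Qiagen column kit and made into libraries by standard Illumina protocols. Groups and replicate numbers were taken from the labels. Per the file headers, each library came from a different mouse.

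The deposited values are whole-number read counts per Ensembl gene, 37991 genes per library, with no normalization. Per the submitters' processing notes, FastQC, TopHat, Cufflinks and Cuffdiff were used with the mouse build NCBIM37, with no versions. The counting program, its treatment of strand and of reads with several matches, and the annotation release are not given in the sources used here. Genes with near-identical copies, such as ribosomal protein genes and mitochondrial transcripts, and genes that overlap on opposite strands are therefore uncertain. One row, Pthlh, carried the letter q in place of an Ensembl identifier and was kept under its symbol. The genome annotation at hand (GENCODE, a later build) differs from NCBIM37, so no coordinates are given; it was used only for gene names, for the chromosome of a gene and for gene order. Of the 12597 tested identifiers, 12283 (97.5%) were found in it.

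Total counts per library were 55770466, 63836457 and 49652545 in WT replicates 1 to 3, 57218077, 47275731 and 45177989 in HET and 48693392, 62472705 and 60025911 in NULL. A single read was worth 0.0157 to 0.0221 CPM. Genes with at least 1 CPM in at least 3 of the 9 libraries were tested, 12597 in all, which held at least 99.82% of the reads of each library.

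The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, 1 fit to all 9 libraries and no covariates, and Benjamini-Hochberg adjusted p-values with a threshold of 0.05. The design written before the data were examined assumed FPKM and limma, and named edgeR for the case that the files held counts, which they did. The labels give no shared litter, batch or day, and the file headers name a different mouse for each library. From the data, the 3 same-numbered pairs of HET and NULL libraries deviated together from their group means (r = 0.163 to 0.319 over genes), and the 6 pairs of other numbers did not (-0.255 to -0.0339). Centring on the group means forces the latter to be negative on balance when the former are positive. The latter range therefore adds no separate support. HET and NULL were treated as paired by number, by the rule that the r of each same-numbered pair exceed 0.1. These pairs enter an added fit with a block and the sorting of the splits. The main fit and the exact permutations over all splits do not use them. The pairing is a hint from the data, since pairs of WT with libraries of other numbers reached similar values (-0.173 to 0.278). HET replicate 3 also correlated more with WT replicate 2 (0.236) than with NULL replicate 3 (0.163). The 6 same-numbered pairs that include WT did not deviate together (-0.241 to 0.012). Contrasts were NULL against WT, HET against WT, NULL against HET, NULL against WT and HET together, any difference between the 3 genotypes, and a slope over the number of floxed alleles (0, 1 or 2). DESeq2 1.42.0 was run beside it and gave no adjusted p for 31 genes (39 for the slope), which were left out of its counts. Levels are means of CPM with TMM factors ± SD; levels of markers of other cell types are CPM without these factors. Ctnnd1 was also tested by exact two-sided permutation of mean log2 CPM. Exact permutations cover the libraries at hand, and counting error is contained in the spread between them.

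Before the data were examined, 42 gene lists were fixed, covering cell junctions, cell identity, other pancreatic and stromal cell types, signalling, matrix, growth, metabolism and technical controls. The 38 lists with at least 5 measured members were tested with limma's camera (limma 3.58.1) at its preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Members were also adjusted over the list alone, and the text calls this p list-adjusted.

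The naming rule, fixed before the data were examined, took for each pairwise comparison Ctnnd1, the 8 largest rises and falls past the threshold whose groups did not overlap (leaving out predicted genes and pseudogenes; where none passed in a direction, the 4 with the smallest p), Cdh1, Ctnnb1, Ctnna1, Jup and Vim, and the 4 members with the smallest p of each list described. The lists described were those past camera's threshold, at least 6 per comparison, and those of junctions and EMT.

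Alternatives planned before the data were examined were no filter on low counts, a mean of at least 5 CPM, DESeq2 size factors, quantile normalization, only the groups compared, the replicate number as a block, library weights, robust moderation, a pseudocount of 0.1, DESeq2, and leaving out each library in turn. After the data were seen, 4 were added: limma on log2(CPM + 1), the presence of Y-linked transcripts as a term, WT replicates 1 and 2 summed into 1 library, and the replicate number as a block within HET and NULL for the contrasts that involve both. Quantile normalization, library weights and the pseudocounts were run with limma-trend on log2 CPM.

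The procedures were tested on simulated counts for the contrast of NULL with WT, drawn for the 12597 genes. edgeR recovered 46.3%, 86.6% and 93.9% of genes changed by 1, 2 and 3 log2 units, with 5.95% false calls, and called 0 genes in data without change. DESeq2 recovered 65.7%, 91.0% and 100% with 19.3% false calls, and called 33 genes in data without change. Camera called the 1 planted list, and 0 lists without change. The genes were simulated independently of each other, whereas the estimated correlation within the real lists had a median of 0.104. The simulation therefore cannot tell how often camera at its preset correlation calls real lists falsely. It also held no differences between libraries beyond the planted changes and independent noise, such as those of sex. The recovery and false-call rates of genes apply to such data and may differ for the real libraries.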

Results

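Gene expression was measured by RNA-seq in cultured mouse pancreatic ductal cells that differed in the number of floxed alleles of Ctnnd1, the gene of p120 catenin (p120ctn). This protein binds the cytoplasmic tail of classical cadherins and stabilises them at the cell surface. The ductal cells came from mice carrying a Cre-activated Kras G12D allele together with no floxed Ctnnd1 allele (WT), 1 floxed allele (HET) or 2 floxed alleles (NULL). Cre recombinase, delivered to the cultures by a lentivirus, was to switch on the mutant Kras and excise the floxed segment of Ctnnd1. The groups thus differed by design in p120ctn, and excision itself was not measured. Each group had 3 libraries, 9 in all. The file headers named a different mouse for each library. The edgeR, DESeq2 and exact permutation p-values below therefore measure the spread between cultures of different mice. Camera's p-values at the preset correlation set a list's genes against the other genes. With a fixed correlation they do not measure how far the list as a whole varies between mice. The p-values for genes on chromosome 2 also count genes, not mice. The libraries held 45177989 to 63836457 counts, and 12597 genes reached at least 1 CPM (a count scaled to the total of its library) in at least 3 libraries. Y-linked transcripts were present in WT replicate 3, HET replicate 1 and HET replicate 2, with 8597, 10572 and 8310 counts, and at 4 to 17 counts in the other 6 libraries, among them all 3 NULL libraries.

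Ctnnd1 (ENSMUSG00000034101) was measured first, because the deleted gene checks the genotype labels. Its level was 1120 CPM ± 328 (SD, n = 3) in WT, 741 ± 161 in HET and 329 ± 90.3 in NULL. The WT libraries held 790, 1132 and 1446 CPM, the HET libraries 864, 559 and 799, and the NULL libraries 426, 247 and 314, so that each NULL library lay below all 6 others. In an exact two-sided permutation test over the 84 splits of the 9 libraries, NULL lay 1.47 log2 units below the other libraries (difference -1.47, p = 0.0119, the smallest p this design allows). NULL held 29.3% of the WT level (log2 fold change -1.77, SE 0.281), which missed the threshold over all genes in edgeR's quasi-likelihood test (adjusted p = 0.0898) but passed when adjusted over the list alone, the 9 measured p120-family and catenin genes (list-adjusted p = 0.00156). The HET mean was 66.0% of WT (log2 fold change -0.60, SE 0.274, edgeR adjusted p = 0.737), and the NULL mean was 44.4% of HET (-1.17, SE 0.277, edgeR adjusted p = 0.259, and 0.0221 adjusted over the list alone). Exact permutation tests of 3 against 3 libraries cannot give a p below 0.1 and gave 0.1 for NULL against WT, 0.3 for HET against WT and 0.1 for NULL against HET. These counts cover the whole gene, including exons outside the floxed segment, so the level left in NULL does not measure intact p120ctn mRNA or protein. Cells that kept an unexcised allele could also contribute to it, since excision was not measured.

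**Figure D1:**
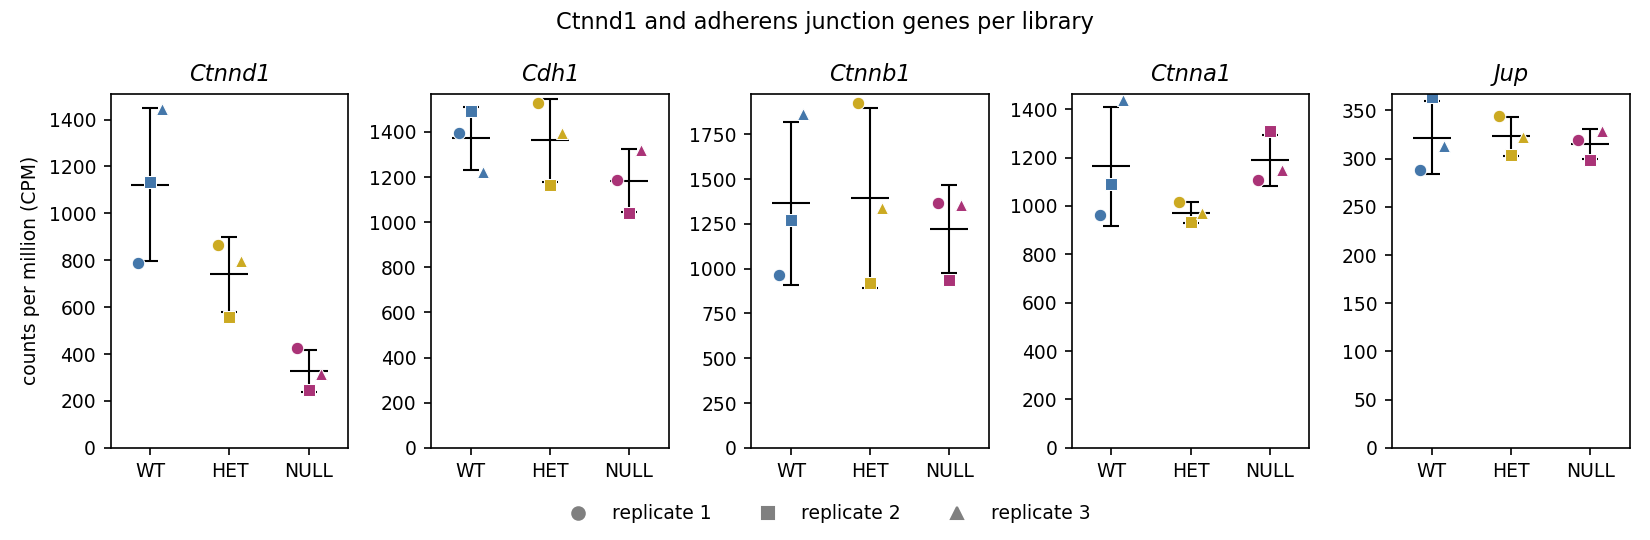
Level of Ctnnd1 and of 4 adherens junction genes in CPM (linear axis from 0) for the WT, HET and NULL groups. Each symbol is 1 library, shaped by replicate number, and the bars give the mean ± SD of 3 libraries; Ctnnd1 lay between 247 and 426 CPM in NULL and between 790 and 1446 CPM in WT, while the WT and NULL ranges of Cdh1, Ctnnb1, Ctnna1 and Jup overlapped. Those of HET and NULL did so too except for Ctnna1 (973 CPM ± 41.7 in HET and 1190 ± 106 in NULL).

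The comparison of NULL with WT asked what the intended loss of both p120ctn alleles changes in ductal cells with the Kras G12D allele. Rnf130 (ENSMUSG00000020376), which encodes a RING-type ubiquitin ligase, fell from 14.1 CPM ± 2.43 (SD, n = 3) in WT to 1.96 ± 0.243 in NULL, 7.22-fold lower (log2 fold change -2.85, SE 0.187, edgeR adjusted p = 0.00199). Jag1 (ENSMUSG00000027276), a ligand of Notch receptors, fell from 84.6 CPM ± 4.08 to 33.0 ± 1.14. Jun (ENSMUSG00000052684), a subunit of the AP-1 transcription factor, fell from 62.9 CPM ± 4.72 to 36.0 ± 2.0. Glipr1 (ENSMUSG00000056888) fell from 128 CPM ± 6.3 to 62.1 ± 7.64. Fam174b (ENSMUSG00000078670) fell from 1.86 CPM ± 0.726, with 66 to 166 counts per library, to 0.138 ± 0.0336, with 5 to 10 counts per library.

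The log2 fold changes were -1.36 for Jag1 (SE 0.142, edgeR adjusted p = 0.0281), -0.80 for Jun (SE 0.0865, 0.0281), -1.05 for Glipr1 (SE 0.122, 0.0348) and -3.72 for Fam174b (SE 0.421, 0.0342). The predicted gene Gm10451 (ENSMUSG00000073000), which the naming rule leaves out and which was chosen after its values were seen, was the sixth gene past the threshold and rose. It had 1 to 4 counts in each WT library (0.0398 CPM ± 0.0218) and 349 to 495 in each NULL library (7.64 CPM ± 0.45; edgeR adjusted p = 0.0112). Among rises that missed the threshold, the smallest unadjusted p-values belonged to Bub1, a kinase of the spindle checkpoint (69.6 CPM ± 3.95 in WT and 121 ± 15.5 in NULL), to Ahcy, which hydrolyses S-adenosylhomocysteine (48.5 ± 1.25 and 87.9 ± 15.2), to Pthlh, which encodes parathyroid hormone-related protein (0.188 ± 0.126 and 11.6 ± 8.43), and to Ism1 (1.99 ± 0.51 and 6.85 ± 1.38). Each of these 4 had an edgeR adjusted p of 0.0833.

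In all, 6 genes passed the threshold, 1 higher and 5 lower in NULL. 2019 genes (16.0% of those tested, against 5% expected by chance) had an unadjusted p under 0.05. DESeq2 called 619 genes, 339 higher and 280 lower. The 2 groups did not overlap at 2486 genes (19.7%), where chance gives 10%. The count of 6 was 1 without WT replicate 1, WT replicate 2, WT replicate 3 or NULL replicate 2, 2 without HET replicate 1, 10 without HET replicate 2 or NULL replicate 1, and 39 without NULL replicate 3. Rnf130 passed in all 9 fits that left out 1 library, and each of the other calls ended in 4 to 7 of its fits. Fam174b had 6 such fits and passed in 2, since it missed the filter on low counts when a WT library was left out. With Y-linked transcripts as a term of the model, the calls of Jun and Fam174b ended. With the replicate number as a block over all 9 libraries the count was 2, and the calls of Jag1, Jun, Glipr1 and Fam174b ended. With WT replicates 1 and 2, the most highly correlated pair of libraries, summed into 1, the count was 1.

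**Figure D2:**
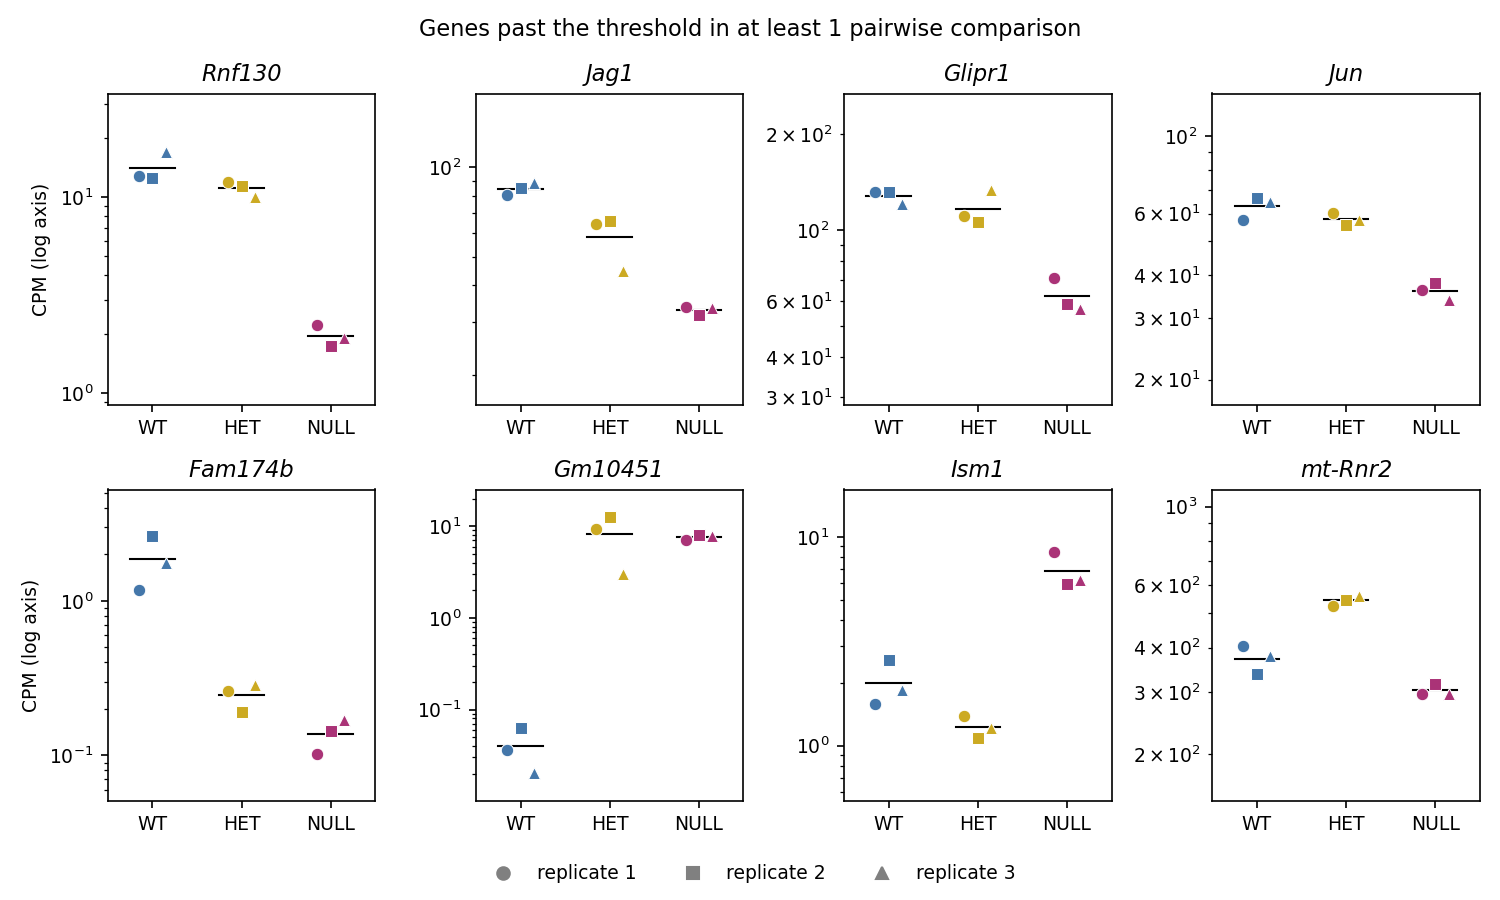
Level in CPM (log axis) of the 8 genes past the threshold in at least 1 pairwise comparison. Each symbol is 1 library and the horizontal line is the mean of the 3 libraries of a group; Rnf130 averaged 1.96 CPM in NULL against 14.1 in WT and 11.1 in HET, and Gm10451 averaged 0.0398 CPM in WT against 8.27 in HET and 7.64 in NULL.

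Genes of the cell cycle rose together in NULL relative to WT. All 44 measured members of this list had a positive log2 fold change (median 0.57), none passed over all genes, and 38 rose when adjusted over the list alone. Among them were Bub1 (list-adjusted p = 0.00304), the mitotic kinesin Kif11 (47.3 CPM ± 2.71 in WT and 86.3 ± 12.1 in NULL, 0.00341) and cyclin A2, Ccna2 (85.0 ± 11.9 and 157 ± 36.7, 0.00812). The list passed camera's test with its preset correlation (adjusted p = 3.15e-23) and did not pass with an estimated correlation (adjusted p = 0.539). The 3 NULL libraries differed widely: the mean log2 level of the list, centred over all 9 libraries, was 0.383, 0.564 and -0.0476 in NULL and -0.227, -0.119 and -0.493 in WT.

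Genes of cholesterol and fatty acid synthesis rose as well, with 27 of 28 measured members positive (median log2 fold change 0.45) and 15 past the threshold when adjusted over the list alone. Cyp51, which demethylates lanosterol, stood at 209 CPM ± 11.5 in WT and 310 ± 22.3 in NULL (0.57 on the log2 scale, SE 0.0905, list-adjusted p = 0.00488). Idi1, an isomerase of the isoprenoid pathway, stood at 42.5 ± 5.75 and 73.2 ± 12 (0.00918). Insig1, which retains the sterol sensor complex in the endoplasmic reticulum, stood at 125 ± 9.61 and 198 ± 19.8 (0.0219). Camera's adjusted p was 1.38e-12 with the preset correlation, and the adjusted p was 0.440 with an estimated correlation. Ribosomal protein genes also rose by that test, with 38 of 41 positive and a median of only 0.11 (adjusted p = 0.00669, and adjusted p = 0.924 with an estimated correlation), and none passed singly even when adjusted over the list alone. Counts of these genes are uncertain, since they share sequence with many processed pseudogenes. The centred mean log2 level of the ribosomal list was higher in WT replicate 1 (0.112) than in all 3 NULL libraries (-0.0574, 0.0651 and 0.032). The ribosomal call ended without WT replicate 2, WT replicate 3, NULL replicate 2 or NULL replicate 3 (adjusted p = 0.383, 0.206, 0.0575 and 0.093).

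Receptor tyrosine kinases and their ligands fell in NULL relative to WT, with 18 of 24 measured members negative (median log2 fold change -0.36). Their summed level, which the most abundant members set, overlapped (2693 CPM ± 326 in WT and 2616 ± 438 in NULL) and was highest of all 9 libraries in NULL replicate 2 (3020 CPM). Pdgfb, a platelet-derived growth factor chain, fell when adjusted over the list alone, from 45.4 CPM ± 23.5 to 12.5 ± 2.44 (list-adjusted p = 0.0338). The epidermal growth factor receptor gene Egfr stood at 253 ± 35.4 in WT and 158 ± 32.7 in NULL without passing (0.0582). Integrin and focal adhesion genes fell, with 21 of 26 negative (median -0.23), and 2 passed when adjusted over the list alone. They were Fermt1, the gene of the integrin activator kindlin-1 (189 ± 52.6 and 69.5 ± 25.7, list-adjusted p = 0.0273), and Tns1, the gene of the actin-binding protein tensin-1 (19.9 ± 4.89 and 6.34 ± 2.82, list-adjusted p = 0.0273). Transcripts of the mitochondrial genome fell, with all 15 negative (median -0.27) and none past the threshold when adjusted over the list alone. The 3 camera adjusted p-values were 0.0024, 0.00497 and 0.00142 with the preset correlation, and with an estimated correlation the adjusted p-values were 0.253, 0.440 and 0.801. The mitochondrial call ended without WT replicate 1 (adjusted p = 0.103). Of these 6 lists, the receptor list alone passed fry, which tests whether a list's genes move on balance in 1 direction (adjusted p = 0.0425).

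**Figure D3:**
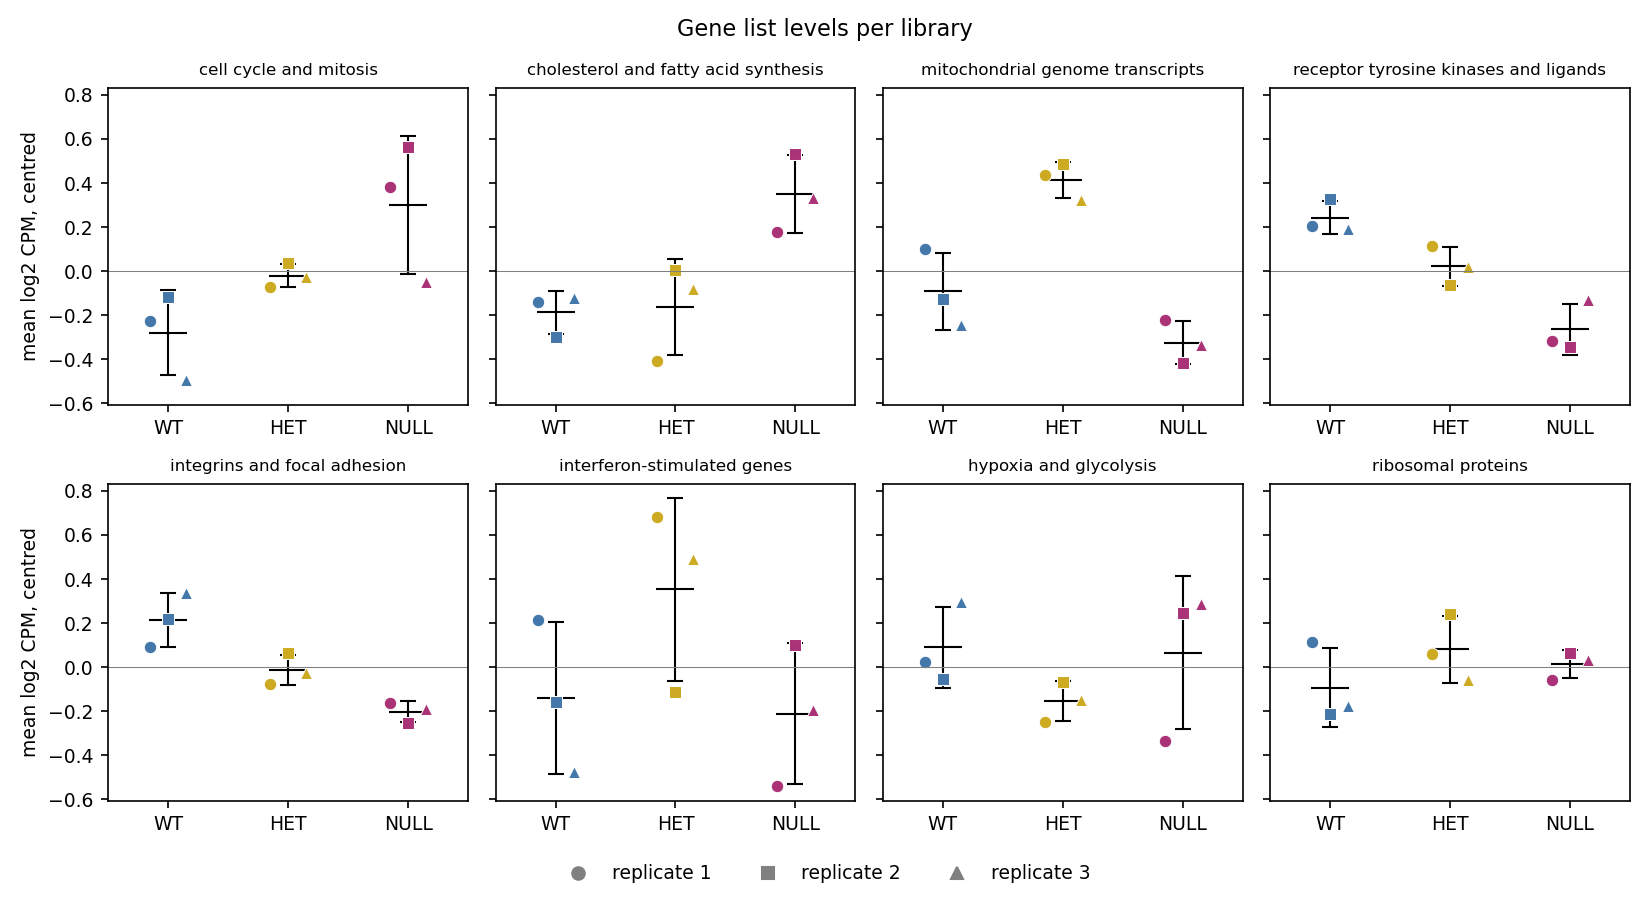
Mean log2 CPM of the measured members of 8 gene lists, centred on the mean of the 9 libraries, by group. Each symbol is 1 library and the bars give the mean ± SD of 3 libraries; the mitochondrial genome list averaged 0.415 in HET, -0.0907 in WT and -0.324 in NULL, and the receptor tyrosine kinase list 0.242 in WT and -0.264 in NULL.

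The lists of junction genes that p120ctn acts with did not pass camera between NULL and WT. E-cadherin (Cdh1) stood at 1370 CPM ± 138 in WT and 1180 ± 140 in NULL (log2 fold change -0.21, SE 0.137, edgeR adjusted p = 0.490) and beta-catenin (Ctnnb1) at 1360 ± 457 and 1220 ± 244 (-0.16, SE 0.313, 0.847). Alpha-catenin (Ctnna1) stood at 1160 ± 247 and 1190 ± 106 (0.03, SE 0.149, 0.944) and plakoglobin (Jup) at 322 ± 38.2 and 315 ± 15.5 (-0.03, SE 0.105, 0.924). The signs for Ctnnb1, Ctnna1 and Jup turned under other settings or when 1 library was left out. The tight junction list had 17 of 23 members negative (camera adjusted p = 0.287, and adjusted p = 0.664 with an estimated correlation). Its summed level was nonetheless lower in each NULL library (5444 to 5609 CPM) than in each WT library (5996 to 6435) and each HET library (6054 to 6190). The mean log2 level of the list averaged lower in NULL than in the other 6 libraries (exact two-sided permutation p = 0.0357, not adjusted over the 38 lists, of which 7 were under 0.05), but NULL replicate 2 (0.0264, centred over the 9 libraries) lay above HET replicate 1 (-0.0242) and HET replicate 3 (0.023). The same test gave 0.1 for NULL against WT, the smallest p that 3 against 3 libraries allow, and 0.3 for NULL against HET. F11r, the gene of junctional adhesion molecule A, fell when adjusted over the list alone (324 CPM ± 23.7 and 241 ± 12.8, list-adjusted p = 0.0328). Claudin-4 (Cldn4) stood at 921 ± 146 and 574 ± 137 (list-adjusted p = 0.0533). Of the 9 measured genes of the p120 family and core catenins, Ctnnd1 alone passed when adjusted over the list alone (camera adjusted p = 0.896; the median of 0.03 and mean of 0.13 were positive and the test negative). None of the 20 classical cadherin and adherens junction genes passed (camera adjusted p = 0.835), nor any of the 18 genes of desmosomes and hemidesmosomes (0.944).

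Vimentin (Vim), a mesenchymal intermediate filament gene, stood at 17.9 CPM ± 15.4 in WT and 24.2 ± 18.8 in NULL (log2 fold change 0.43, SE 0.674, edgeR adjusted p = 0.802), and its sign turned without NULL replicate 1 (-0.42). None of the 14 measured genes of the mesenchymal and epithelial-mesenchymal transition (EMT) list passed when adjusted over the list alone. The list's median log2 fold change was 0.25, its mean -0.18 and its test negative (camera adjusted p = 0.637) with 14 of the 32 listed genes measured.

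HET was compared with WT to ask what the intended removal of a single p120ctn allele changes. Gm10451, named outside the rule as above, was the only gene past the threshold and rose to 8.27 CPM ± 4.85 in HET (137 to 589 counts per library; edgeR adjusted p = 0.0203). None of the genes covered by the naming rule passed. The rises with the smallest p-values were those of the mitochondrial ribosomal RNA mt-Rnr2 (373 CPM ± 33.8 in WT and 543 ± 17.2 in HET, edgeR adjusted p = 0.539), the glutamate transporter gene Slc1a1 (1.47 ± 0.432 and 10.3 ± 6.09, 0.539), Pthlh (3.81 ± 2.22 in HET, 0.539) and mt-Nd2 (1460 ± 144 and 2110 ± 20.4, 0.633). Among lower values, Fam174b (0.246 ± 0.0486 in HET) and the mitochondrial glycerol-3-phosphate dehydrogenase gene Gpd2 (312 ± 58.4 and 158 ± 16.4) had an edgeR adjusted p of 0.383. The nuclear receptor gene Nr4a2 (39.8 ± 13.0 and 13.8 ± 0.96) and the alpha-synuclein gene Snca (7.09 ± 0.848 and 2.23 ± 0.602) had one of 0.539. Cdh1, Ctnnb1, Ctnna1, Jup and Vim did not pass (adjusted p = 0.991, 0.988, 0.741, 0.992 and 0.749). The log2 fold changes of Cdh1 (-0.01), Ctnnb1 (0.03) and Jup (0.01) changed sign under other settings.

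At an unadjusted p under 0.05 there were 859 genes (6.82%) between HET and WT, and DESeq2 called 67, 32 higher and 35 lower. The groups did not overlap at 1839 genes (14.6%, against 10% by chance). The edgeR count of 1 was 0 without WT replicate 1, WT replicate 2, WT replicate 3, HET replicate 1, NULL replicate 2 or NULL replicate 3, 2 without NULL replicate 1 and 8 without HET replicate 2.

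Transcripts of the mitochondrial genome rose in HET relative to WT, all 15 of them positive (median log2 fold change 0.48) and all 15 past the threshold when adjusted over the list alone. They included mt-Rnr2 (list-adjusted p = 0.00367) and the ATP synthase subunit genes mt-Atp6 (580 CPM ± 84.3 and 856 ± 48.0, 0.00527) and mt-Atp8 (329 ± 55.1 and 491 ± 27.5, 0.00527). The share of all counts from mitochondrial genes was 4.305%, 4.349% and 3.803% in the HET libraries and 3.419%, 2.866% and 2.625% in the WT libraries. The nuclear genes of oxidative phosphorylation rose by less, 28 of 36 positive with a median of 0.08 and none past the threshold when adjusted over the list alone. The centred mean log2 level of this nuclear list was higher in WT replicate 1 (0.0612) than in HET replicates 1 and 3 (0.00338 and 0.0508). Camera's adjusted p was 3.52e-18 for the mitochondrial genome and 8.41e-04 for oxidative phosphorylation, and with an estimated correlation the adjusted p-values were 0.559 and 0.569. The oxidative phosphorylation call ended without WT replicate 3 (adjusted p = 0.0607).

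Cell cycle genes rose in HET, with 42 of 44 positive (median 0.25), ribosomal protein genes with 38 of 41 (median 0.18), and interferon-stimulated genes with 26 of 30 (median 0.39). None of their members passed when adjusted over the list alone. The antiviral synthetase gene Oas2 stood at 1.78 CPM ± 0.537 in WT and 5.51 ± 3.29 in HET (0.267). Their camera adjusted p-values were 4.82e-09, 3.95e-08 and 7.83e-05, and the adjusted p was 0.569 for each with an estimated correlation. The groups overlapped in the centred mean log2 level of 2 of these lists. WT replicate 1 lay above HET replicates 1 and 3 for ribosomal protein genes (0.112 against 0.059 and -0.0602). It lay above HET replicate 2 for interferon-stimulated genes (0.212 against -0.113). Hypoxia and glycolysis genes fell, 30 of 32 negative (median -0.15). The glucose transporter gene Slc2a1 was past the threshold when adjusted over the list alone (394 ± 34.4 and 275 ± 8.63, list-adjusted p = 0.0321). The list had a camera adjusted p of 7.23e-04, and adjusted p = 0.569 with an estimated correlation. Without WT replicate 3 the calls of the interferon and hypoxia lists ended (adjusted p = 0.0607 and 0.0878).

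The EMT list fell in HET, with 9 of 14 members negative (median -0.38). Loxl2, a lysyl oxidase that cross-links collagen, fell when adjusted over the list alone (16.8 CPM ± 8.44 in WT and 3.87 ± 1.27 in HET, list-adjusted p = 0.018). Fibronectin (Fn1) stood at 1080 ± 348 and 498 ± 183 (0.0712). All 4 measured fibroblast markers had lower means in HET as well, without passing over all genes (edgeR adjusted p = 0.697 to 0.919). Lower values also prevailed among integrin genes (21 of 26, median -0.18), Rho family and actomyosin genes (25 of 33, median -0.08) and receptor tyrosine kinases (17 of 24, median -0.25). These lists fell by camera with no member past the threshold when adjusted over the list alone. The camera adjusted p-values of the 4 lists were 0.0119, 0.0143, 0.0174 and 0.0459, and with an estimated correlation the adjusted p-values were 0.569, 0.559, 0.569 and 0.559. Calls ended for the EMT list without HET replicate 3 (adjusted p = 0.0521) and without a filter on low counts (0.0741), and for integrins without WT replicate 2 or WT replicate 3 (0.0542 and 0.07). Calls also ended for the Rho list without WT replicate 2, WT replicate 3 or HET replicate 1 (0.0768, 0.0903 and 0.129), and for receptors without any WT library, HET replicates 2 or 3, or NULL replicates 1 or 3 (0.0607 to 0.21) and with WT replicates 1 and 2 summed (0.0857).

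Of the markers of other cell types, the endothelial list rose in HET, all 5 of its measured members positive (median 0.39; camera adjusted p = 0.0278, and adjusted p = 0.569 with an estimated correlation). Von Willebrand factor (Vwf) passed when adjusted over the list alone (0.432 CPM ± 0.24 in WT and 1.97 ± 0.791 in HET, list-adjusted p = 0.0282). The most abundant member, the transcription factor gene Sox17, stood at 92.7 ± 46.0 and 144 ± 32.9. This call ended without WT replicate 1, WT replicate 2 or HET replicate 2 (adjusted p = 0.286, 0.0924 and 0.0566). The list kept 5 measured members in only 6 of the 9 fits that left out 1 library and was not tested in the others. It also ended without a filter on low counts (0.922), with Y-linked transcripts as a term of the model (0.215) and with WT replicates 1 and 2 summed (0.169). The junction lists did not pass between HET and WT: camera's adjusted p was 0.948 for the p120 family and core catenins (median and mean positive, test negative), 0.932 for classical cadherins, 0.733 for tight junctions and 0.948 for desmosomes (median and test negative, mean 0.05). With 11 of the 38 tested lists past camera's threshold and none with an estimated correlation, the calls between HET and WT rest on the preset correlation.

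NULL was compared with HET to ask what the intended loss of the remaining p120ctn allele changes. Rnf130 fell from 11.1 CPM ± 1.0 in HET to 1.96 ± 0.243 in NULL (log2 fold change -2.51, SE 0.184, edgeR adjusted p = 0.00522). The secreted factor gene Ism1 (ENSMUSG00000074766) rose from 1.23 ± 0.148 to 6.85 ± 1.38 (2.48, SE 0.267, 0.0398), and mt-Rnr2 (ENSMUSG00000064339) fell from 543 ± 17.2 to 303 ± 11.7 (-0.84, SE 0.0911, 0.0398). These 3 genes were the edgeR calls. 1567 genes (12.4%) had an unadjusted p under 0.05 and DESeq2 called 295, 130 higher and 165 lower. Counts of mt-Rnr2 are uncertain, since nuclear copies of the mitochondrial genome share its sequence and the counting of reads with several matches is not given in the sources used here. The count of 3 was 1 without WT replicate 1, WT replicate 2, WT replicate 3 or HET replicate 1, 14 without NULL replicate 1 and 0 without NULL replicate 2 or NULL replicate 3. The call of mt-Rnr2 ended in each of the 9 fits that left out a library. Libraries of HET and NULL with the same replicate number deviated together from their group means (r = 0.163 to 0.319). With the replicate number as a block within these groups Rnf130 passed (log2 fold change -2.51, edgeR adjusted p = 0.0239). The calls of Ism1 (2.47, 0.0966) and mt-Rnr2 (-0.84, 0.129) ended in that fit, and with the block over all 9 libraries edgeR called 0 genes. With Y-linked transcripts, which HET replicates 1 and 2 carried and no NULL library did, as a term of the model, the calls of Ism1 and mt-Rnr2 ended. The groups did not overlap at 2344 genes (18.6%, against 10% by chance).

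Mitochondrial genome transcripts fell in NULL relative to HET, with all 15 negative (median log2 fold change -0.74), all 15 past the threshold when adjusted over the list alone and mt-Rnr2 past it over all genes. Nd subunits of respiratory complex I followed, with mt-Nd2 at 2110 CPM ± 20.4 in HET and 1170 ± 145 in NULL (list-adjusted p = 3.72e-04) and mt-Nd5 at 3280 ± 375 and 1770 ± 186 (4e-04). Cholesterol and fatty acid synthesis genes rose, 28 of 28 positive (median 0.34). The desaturase gene Scd2 (1130 ± 351 and 2360 ± 452, list-adjusted p = 0.0431), Insig1 (0.0431) and the ATP citrate lyase gene Acly (383 ± 19.0 and 498 ± 34.2, 0.0431) passed when adjusted over the list alone. Cell cycle genes rose, 44 of 44 positive (median 0.34), with none past the threshold when adjusted over the list alone. NULL replicates 1 and 2 carried this rise (centred mean log2 level 0.383 and 0.564). NULL replicate 3 (-0.0476) lay below HET replicates 2 and 3 (0.0357 and -0.0265) and above HET replicate 1 (-0.0705). The 3 camera adjusted p-values were 4.49e-21, 2.05e-12 and 2.2e-11, and with an estimated correlation the adjusted p-values were 0.454, 0.677 and 0.782. The mitochondrial list alone passed fry (adjusted p = 0.0104).

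Interferon-stimulated genes fell in NULL relative to HET, with 26 of 30 negative (median -0.52) and none past the threshold when adjusted over the list alone (camera adjusted p = 1.51e-04, and adjusted p = 0.782 with an estimated correlation). Exact two-sided permutation of the list's mean log2 level over the libraries of both groups gave p = 0.2. The libraries stood apart within the groups: the centred mean log2 level of this list was 0.682, -0.113 and 0.491 in HET and -0.541, 0.0998 and -0.194 in NULL, and its summed level was highest of all 9 libraries in NULL replicate 2 (958.1 CPM). Hypoxia and glycolysis genes rose, 27 of 32 positive (median 0.24). NULL replicates 2 and 3 carried this rise (centred mean log2 level 0.244 and 0.286), while NULL replicate 1 (-0.334) lay below all HET libraries (-0.247, -0.0657 and -0.15). Pfkfb4, which sets the level of fructose 2,6-bisphosphate (8.80 CPM ± 3.28 and 40.0 ± 21.0), and the hypoxia factor gene Hif1a (133 ± 14.6 and 183 ± 18.7) passed when adjusted over the list alone (list-adjusted p = 0.0375 for each). Camera's adjusted p was 0.00193 with the preset correlation, the adjusted p was 0.782 with an estimated correlation, and the call ended without NULL replicate 3 (adjusted p = 0.219). Gastric and metaplasia mucin genes had 7 of 8 members negative (median -1.84) without passing as a list (camera adjusted p = 0.138). HET replicate 2 stood apart, with a centred mean log2 level of -1.13 against 1.72 and 1.13 in the other HET libraries and -0.321, -0.569 and -0.359 in NULL. The mucin gene Muc1 (122 ± 57.0 and 19.6 ± 15, list-adjusted p = 0.0441), Onecut2 (78.7 ± 54.2 and 16.0 ± 6.05, 0.0495) and the cathepsin E gene Ctse (44.3 ± 36.1 and 14.3 ± 3.33, 0.0495) fell when adjusted over the list alone.

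Among junction genes, F11r (321 CPM ± 21.7 in HET and 241 ± 12.8 in NULL, list-adjusted p = 0.0406) and Cldn4 (927 ± 60.1 and 574 ± 137, 0.0497) fell when adjusted over the list alone. The tight junction list did not pass (camera adjusted p = 0.431). The p120 family (0.749), classical cadherins (0.794; median and mean positive, test negative), desmosomes (0.895; median 0.01, mean -0.01, test positive) and EMT genes (0.216) did not pass either. Cdh1, Ctnnb1, Ctnna1, Jup and Vim had edgeR adjusted p-values of 0.566, 0.827, 0.463, 0.909 and 0.430. The signs of Ctnnb1 and Jup turned when 1 library was left out.

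Setting NULL against the WT and HET libraries together asked what distinguishes cultures with 2 floxed Ctnnd1 alleles from cultures with at most 1. Rnf130, Jag1, Jun and Glipr1 fell and Ism1 rose in NULL (edgeR adjusted p = 0.00184, 0.0360, 0.0274, 0.0360 and 0.0274). Of the 7 genes past the threshold, 3 rose and 4 fell, while 2075 (16.5%) had an unadjusted p under 0.05 and DESeq2 called 665. The contrast averages the log2 levels of WT and HET, so a gene that differs only from WT can pass. Gm10451, named outside the rule as above, was 1 of the 3 rises (log2 fold change 3.673, edgeR adjusted p = 0.036). Its mean in NULL nonetheless lay below that in HET, so it does not set NULL apart from both groups. With the replicate number as a block within HET and NULL, these 7 genes passed among 30 (16 higher and 14 lower). With the block over all 9 libraries only Rnf130 passed (adjusted p = 0.0396), and with Y-linked transcripts as a term the count was 3, all lower, and Jag1, Jun and Ism1 were lost (0.0695, 0.0695 and 0.0837). The count was 2 without WT replicate 1, WT replicate 2 or NULL replicate 2, 1 without WT replicate 3, HET replicate 1 or NULL replicate 3, 3 without HET replicate 3 and 18 without NULL replicate 1.

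A test for any difference between the 3 genotypes called 7 genes, among them Rnf130 (edgeR adjusted p = 0.00623), Jag1 (0.0488), Jun (0.0488), Fam174b (0.0468), Ism1 (0.0468) and mt-Rnr2 (0.0488). There were 1712 genes (13.6%) at an unadjusted p under 0.05 and 579 called by DESeq2. With the block within HET and NULL the count was again 7, with Rnf130 and Gm10451 the genes in common (0.0213 and 0.0395). With the block over all 9 libraries edgeR called 0, and with the Y-linked term 3. In leave-outs, that count was 1 without WT replicate 1, WT replicate 2, WT replicate 3 or HET replicate 1, 4 without HET replicate 3 and 0 without NULL replicate 2 or NULL replicate 3. A linear trend with the number of floxed alleles, 0, 1 or 2, was found by edgeR for 0 genes (smallest adjusted p = 0.0537). 1926 genes (15.3%) had an unadjusted p under 0.05 and DESeq2 called 551, 303 rising and 248 falling. The trend count of 0 was 1 without HET replicate 2 or HET replicate 3 and 120 without NULL replicate 3.

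Ductal and epithelial genes were abundant in the cultures and markers of other cell types were mostly near the detection limit. The ductal keratin gene Krt19, which the mesothelial list also holds, averaged 1660 CPM over the 9 libraries. The most abundant acinar marker, the chymotrypsinogen gene Ctrb1, averaged 10.8 CPM, and none of the 24 endocrine markers passed the filter (highest, Scg5, at 0.365 CPM). Fibroblast, leukocyte and mesothelial lists had 4, 2 and 3 measured members and were not tested as groups, with Fbln2 at 1650 CPM, Cd14 at 88.7 and Msln at 2820 their most abundant. Of the 4 fibroblast markers, all had lower means in HET than in WT and 3 had lower means in NULL, and both leukocyte markers were lower in each. Values of the following were chosen after they were seen: Fbln2 (2190 CPM ± 526 in WT, 1300 ± 327 in HET and 1470 ± 403 in NULL), Gas6 (41.7 ± 19.5, 21.2 ± 6.05 and 7.54 ± 2.68), Pdpn (19.9 ± 17.2, 1.82 ± 1.51 and 10.4 ± 9.85), Fbln1 (0.914 ± 0.414, 0.79 ± 0.256 and 1.14 ± 0.0259) and Cd14 (121 ± 35.4, 82.5 ± 26.9 and 62.5 ± 21.3). None of these 5 passed between NULL and WT (edgeR adjusted p = 0.327, 0.0988, 0.83, 0.75 and 0.236) or between HET and WT (0.697, 0.709, 0.741, 0.919 and 0.744). All 14 measured acinar markers were positive in NULL and in HET relative to WT, without passing camera (adjusted p = 0.342 and 0.173). In each group 1 library carried this shift, by the list's centred mean log2 level. These were NULL replicate 1 (0.469, against -0.132 and -0.114) and HET replicate 3 (0.901, against -0.06 and -0.586).

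**Figure D4:**
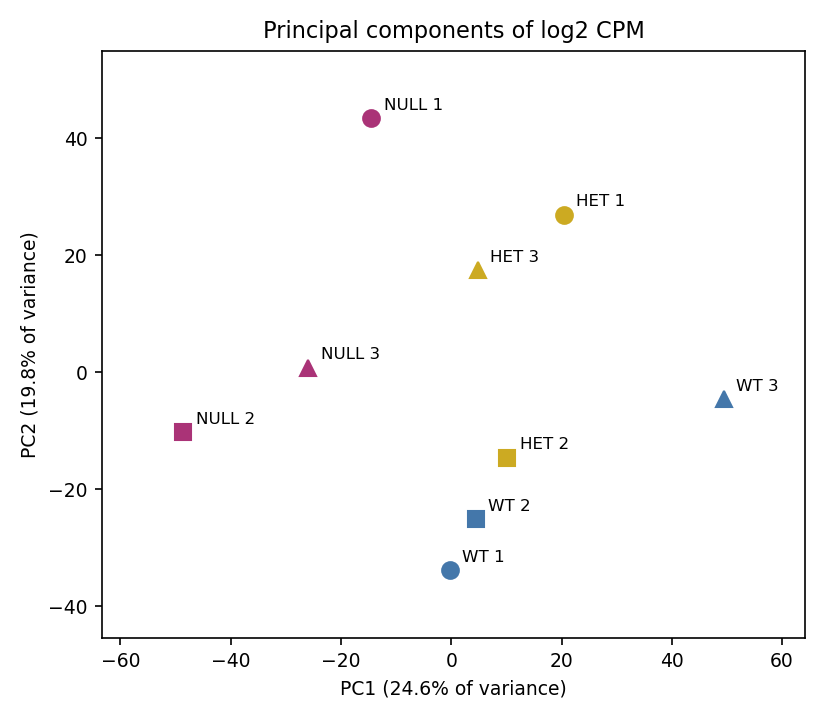
Principal components of log2 CPM over the 12597 genes, with PC1 (24.6% of variance) on the horizontal and PC2 (19.8%) on the vertical axis. Each symbol is 1 library, coloured by group; differences between group means made up 64.3% of the variance along PC1 and 40.3% along PC2, and WT replicates 1 and 2 lay close together.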

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

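Most settings below were planned. Limma on log2(CPM + 1), the Y-linked term, the summing of WT replicates 1 and 2 and the block within HET and NULL were chosen after the data were seen. So was the reading of a list's direction from its mean difference in log2 CPM against other genes (19 of 637 list values then change direction, 28 by the sign of the test). The cause of the differences was not tested, except that fits with fewer libraries or with a block have fewer degrees of freedom. A read was worth at most 0.0221 CPM, and depth limits genes such as Fam174b and Gm10451 with 10 or fewer counts in a library.

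Counts of genes are given in the order NULL against WT, HET against WT, NULL against HET, NULL against the rest, any difference and trend, for which edgeR called 6, 1, 3, 7, 7 and 0. DESeq2 called 619, 67, 295, 665, 579 and 551. Counts that moved by over 1.5 times elsewhere were 14 for NULL against the rest and 1 for the trend without a filter. With a mean of at least 5 CPM they were 1 for NULL against HET, 2 for any difference and 1 for the trend. With DESeq2 size factors they were 4 for any difference and 1 for the trend. Quantile normalization gave 10 for NULL against WT, and for NULL against the rest it gave 2 rises and 8 falls where edgeR gave 3 and 4. Only the groups compared gave 2 for HET against WT and 0 for NULL against HET. Library weights gave 41 for NULL against WT, 5 for NULL against HET, and 16 for any difference and for the trend. The trend was 1 on log2(CPM + 0.1). On log2(CPM + 1), counts were 11, 0, 5 and 11 for the first contrasts and 1 for the trend. With the Y-linked term they were 1 for NULL against HET, 3 for NULL against the rest, 3 for any difference and 1 for the trend. With WT replicates 1 and 2 summed they were 1 for NULL against WT, 0 for HET against WT, 3 for NULL against the rest and 1 for any difference. Leaving out 1 library gave 1 to 39, 0 to 8, 0 to 14, 1 to 18, 0 to 10 and 0 to 120. The 39 and the 120 came without NULL replicate 3, the 8 and the 10 without HET replicate 2 and the 14 and the 18 without NULL replicate 1. Counts of 0 are edgeR's or limma's, beside unadjusted counts of 859 for HET against WT, 1567 for NULL against HET, 1712 for any difference and 1926 for the trend in the fit of all libraries.

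Outside the main fit, HET and NULL libraries were treated as paired by number and WT libraries were not. Of the 9 same-numbered pairs, 3 correlated above 0.1, all of them between HET and NULL. In all, 5 of 9 libraries correlated best with their own number. With a block within HET and NULL, edgeR called 2 genes between them, 1 of them Rnf130 (adjusted p = 0.0239), and Ism1 (0.0966) and mt-Rnr2 (0.129) were lost. Ctnnd1 (-1.182, adjusted p = 0.193) and the 5 lists stayed on their side of the threshold, and this block changed no other call, over all genes, of a named gene or of a list between NULL and HET. In the same fit NULL against the rest rose to 30 genes (16 rises and 14 falls), with the 7 among them. Any difference stayed at 7, 2 of them in common, and the trend at 0. With the replicate number as a block for all 9 libraries, the counts were 2 for NULL against WT, 0 for HET against WT, 0 for NULL against HET, 1 for NULL against the rest and 0 for any difference, and 0 for the trend as before. Counts of lists were as without the block.

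Ctnnd1 between NULL and WT passed with library weights (-1.787, adjusted p = 0.0345) and DESeq2 (-1.771, adjusted p = 7.95e-08), and between NULL and HET with DESeq2 (-1.165, adjusted p = 0.00298). Its other adjusted p-values between NULL and WT lay from 0.0682 to 0.249, and from 0.0629 to 0.285 with 1 library left out (log2 fold change -2.0 to -1.549). The permutation result for NULL against the rest was under 0.05 in each setting that gives it (p up to 0.037 with the block, and 0.0179 to 0.0357 with 1 library left out). Only the groups, library weights, robust moderation, DESeq2, the block within HET and NULL and the Y-linked term give no such p.

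Rnf130 passed in 13 of 13 settings between NULL and WT and in 12 of 14 between NULL and HET. There it was lost with only the groups compared, with the block for all 9 libraries, and without NULL replicate 2 or NULL replicate 3 (adjusted p up to 0.0892). Between NULL and WT, Jag1 passed in 11 of 13, Glipr1 in 10 of 13, Jun in 9 of 13, Gm10451 in 12 of 13 and Fam174b in 5 of 11. Jag1 was lost without any WT library, HET replicate 1, NULL replicate 1 or NULL replicate 2 (adjusted p up to 0.2). Glipr1 was lost without any WT library, HET replicate 1 or NULL replicate 2 (up to 0.223), and Jun without any of these or HET replicate 3 or NULL replicate 1 (up to 0.2). Gm10451 was lost without any WT library or NULL replicate 2 (up to 0.108), and Fam174b without HET replicates 1 or 3 or NULL replicates 1 or 2 (up to 0.148). When a WT library was left out, Fam174b missed the filter and was not tested. Between HET and WT, Gm10451 passed in 9 of 13 and was lost without any WT library, HET replicate 1, NULL replicate 2 or NULL replicate 3 (up to 0.23). Between NULL and HET, Ism1 passed in 9 of 13 and in 1 of 9 with a library left out (without NULL replicate 1), and mt-Rnr2 in 8 of 14 and in 0 of 9 (adjusted p up to 0.265 for each).

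Lists past camera's threshold numbered 6 for NULL against WT, 11 for HET against WT and 5 for NULL against HET. They numbered 0, 0 and 0 with an estimated correlation and 1, 0 and 1 with fry. They numbered 5 to 10, 6 to 12 and 4 to 9 with 1 library left out (10 without NULL replicate 1, 6 without WT replicate 3, 9 without HET replicate 3). Other settings stayed within 1.5 times. Exact two-sided permutation of a called list's mean log2 level over the libraries compared cannot give a p below 0.1. Between NULL and WT it gave 0.1 except for mitochondrial (0.2) and ribosomal genes (0.4). Between HET and WT it gave 0.1 except for interferon and Rho genes (0.2) and endothelial, ribosomal and oxidative phosphorylation genes (0.3). Between NULL and HET it gave 0.1 except for interferon (0.2), cell cycle (0.3) and hypoxia genes (0.4).

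Signs that turned belonged to genes and lists that passed in no setting in which they turned. Between NULL and WT they were Ctnnb1 with the Y-linked term (0.01441; leave-outs -0.3582 to 0.1277) and Ctnna1 with WT replicates 1 and 2 summed (-0.05506; leave-outs -0.09087 to 0.2096). Jup turned as well (leave-outs -0.1014 to 0.06812), as did Vim with library weights (-0.3211; leave-outs -0.4177 to 1.396). Between HET and WT, Cdh1 turned with quantile normalization (0.02318), the Y-linked term (0.0439) and the WT sum (0.02918; leave-outs -0.0989 to 0.09164). Ctnnb1 turned with quantile normalization (-0.04678), the block (-0.0005747), the Y-linked term (-0.06308) and the WT sum (-0.09793; leave-outs -0.2727 to 0.3169). Jup turned without a filter (-0.004166) and with library weights (-0.06215; leave-outs -0.06612 to 0.1032), and the p120 relative Ctnnd2 turned with library weights (-0.1332; leave-outs -2.801 to 4.138). Between NULL and HET, Ctnnb1 turned with the Y-linked term (0.07748; leave-outs -0.4179 to 0.1129), Jup with a library left out (-0.07873 to 0.01129) and the P-cadherin gene Cdh3 with the Y-linked term (-0.004519).

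Mean differences of lists turned between NULL and WT for classical cadherins (leave-outs -0.0898 to 0.114) and EMT genes (0.169 without a filter; leave-outs -0.414 to 0.0136). Between HET and WT they turned for the p120 family (-0.0168 without a filter; leave-outs -0.142 to 0.217), classical cadherins (0.0643 with a prior count of 0.1; leave-outs -0.0815 to 0.0294), tight junctions (leave-outs -0.0797 to 0.00602) and desmosomes (-0.00542 without a filter; leave-outs -0.0724 to 0.07). Between NULL and HET they turned for classical cadherins (leave-outs -0.0263 to 0.118) and desmosomes (leave-outs -0.0487 to 0.114).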

Other observations

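The tests of where the changed genes lie, of nuclear respiratory genes and of variants and abundant genes for the mitochondrial transcripts, and of the similarity of WT replicates 1 and 2 were chosen after the result was seen. The splits of the libraries were planned, and their sorting by pairs was not.

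Several lists that did not pass camera still held members that moved when adjusted over the list alone. Extracellular matrix genes went both ways in NULL relative to WT, with 7 rising and 3 falling of 23 measured when adjusted over the list alone (camera adjusted p = 0.601). Squamous and basal genes, a lineage that ductal tumours can take on, had 10 of 13 members positive in NULL (median log2 fold change 0.72; camera adjusted p = 0.0799, and adjusted p = 0.664 with an estimated correlation) and 8 of 13 in HET (median 0.65; 0.0563, and adjusted p = 0.569), each with 2 members rising when adjusted over the list alone. Pancreatic ductal markers had 3 of 19 members falling when adjusted over the list alone both in NULL against WT (camera adjusted p = 0.457) and in NULL against HET (0.256). Genes of antigen presentation by MHC class I had 10 of 12 members negative in NULL against WT without any passing (camera adjusted p = 0.0799). In the list of immediate-early and stress genes, with 15 of 25 negative, Jun was the member past the threshold over all genes (camera adjusted p = 0.0941). Targets of Kras and ERK signalling, whose activating allele all 3 groups carry, had 13 of 25 members positive in NULL against WT (camera adjusted p = 0.757).

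Among the 100 genes with the smallest p between NULL and WT, leaving out Ctnnd1, 20 lay on chromosome 2, the chromosome of Ctnnd1, among them Jag1, Bub1, Ahcy and Ism1, against a median of 8 (one-sided permutation test of 10000 draws matched on mean level, p = 4e-04). It was 10 of the top 50 and 29 of the top 200 (permutation p = 0.007 and 0.003), 9, 13 and 26 of the top 50, 100 and 200 between HET and WT (0.0208, 0.0697 and 0.0162), and 6, 12 and 17 between NULL and HET (0.21, 0.113 and 0.469). The draws argue against chance placement of genes taken as independent (20 against 14 at their upper end), although neighbouring genes are not independent. With the same limit they argue against cell cycle genes as the whole cause (16 against 14 without 993 genes correlated with that list above 0.7). Gain or loss of the whole chromosome is argued against by the median log2 fold change of its 1008 measured genes (-0.00347). Reads lost in NULL at variants of the floxed strain are argued against too (30.0% of these genes fell, against 55.0% of other top genes). The opposite case, reads lost in WT, was not tested. Alleles inherited together with the floxed Ctnnd1 stay open beside effects of p120ctn loss, with top genes being 9 of the 503 in the nearer part of the chromosome by gene order and 11 of the 504 in the farther (Fisher's exact p = 0.822).

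Mitochondrial genome transcripts were lower in NULL than in HET, with WT between them, so the levels did not follow the number of floxed Ctnnd1 alleles. A change in all transcripts of the respiratory chain is argued against by the nuclear-encoded genes (mean log2 difference -0.0421, SD 0.156 over genes), and reads lost at variants of the mitochondrial genome by the uniform size, with 15 of 15 transcripts within 0.3 of the median. A share taken by the 10 most abundant nuclear genes is argued against as well, since these can change the log2 share of the other genes by at most 0.0994 in a library, and the log2 difference in mitochondrial share was -0.716. Mitochondrial DNA content, RNA quality and the growth state of the cultures stay open and were not tested, as does an effect of the genotype.

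WT replicates 1 and 2 correlated at r = 0.9905 over genes, against 0.9291 to 0.9693 for the other pairs of the 36, and no gene differed more than 4-fold between them, against 77 to 184 genes in the other pairs within groups. They were not 1 library deposited as 2, since their counts differed by a median chi-square of 18.6 per gene relative to counting noise (17.2 to 71.2 over all pairs). They were not the closest pair on the typical gene (median absolute log2 difference 0.159, against 0.154 between HET replicates 1 and 3). Shared sex is argued against as the whole cause, since the most similar of the other pairs without Y-linked transcripts reached r = 0.9693. A common litter, culture day or isolation stays open and was not tested.

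Splits of the libraries show which counts chance regrouping can give. For the 3 pairwise contrasts, 10 splits are too few for a share under 0.05. NULL against WT gave 6 genes against at most 1 in another split (1 of 10 splits as large), 619 against 115 with DESeq2 (1 of 10), and 6 lists against 13 (5 of 10). HET against WT gave 1 gene against 9 (3 of 10) and 11 lists against 11 (2 of 10), and NULL against HET gave 3 genes against 6 (3 of 10) and 5 lists against 8 (9 of 10). HET and NULL were treated as paired by number. The 3 other splits that part all 3 pairs, as the real one does, gave at most 1 gene and 8 lists, and the 6 that part fewer pairs gave up to 6 genes and 8 lists. For NULL against the rest, 6 of 84 splits gave 7 or more genes, with 20 the highest other, so chance cannot be excluded for this count over all splits. The 8 splits that part all 3 pairs of HET and NULL, the real one included, are too few for a share under 0.05 (7 against 2), and the 76 others held the 20. The count at an unadjusted p under 0.05, 2075 against 1581, was reached in 1 of 84, the real one. This argues against chance over all splits, though most of them do not part all 3 pairs of HET and NULL. Among the 8 that do, the count was 2075 against 1395, again too few splits. For any difference, 4 of 100 drawn splits reached 7 genes (highest other 14). That share is under 0.05 but close to it, and the real count lies within the range of the other splits, so it is weak evidence against chance. Of these, 43 part all 3 pairs, and 2 of them, the real one included, reached 7 (highest other 7). For the trend, with 0 genes, 100 of 100 did (highest other 7). Other splits that gave several times the real count, such as 9 against 1 and 20 against 7, point to a structure of the libraries that the genotypes do not describe. The 3 libraries with Y-linked transcripts form 1 of the 10 splits for HET against WT and 1 of the 84. Whether these splits gave the 9 and the 20 was not examined.

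HET replicate 1 held 799 counts of Xist, a transcript of the inactive X chromosome, beside its Y-linked counts, where WT replicate 3 and HET replicate 2 held 42 and 9 and the 6 libraries without Y-linked transcripts 27729 to 44599.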
